A study of Mus musculus with 3 samples.

How the data were processed

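Gene expression was measured by messenger RNA sequencing of 3 cultures of mouse bone marrow stromal cells, 1 for each vesicle preparation (All-EV, Ocn-EV and Prx1-EV). Groups were taken from the sample labels. Per the labels' protocols, libraries were made from 100 ng of total RNA with a NEBNext Ultra II RNA kit and sequenced as 150-base read pairs. Vesicles of all 3 groups are described as captured on beads with an HA antibody. The sources used here do not say how that step took up vesicles of the wild-type All-EV mice.

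The deposited table holds 1 signal value per gene and library, which the authors normalised. The submitters' processing notes name FastQC 0.74, Trimmomatic 0.38.1, HISAT2 2.2.1, featureCounts 2.0.3, DESeq2 2.11.40.8 and the mouse build mm10, without giving their order or settings. The number given for DESeq2 has the form of a Galaxy wrapper version, so the version of DESeq2 itself is uncertain. The use of strand in counting is not given in the sources used here, so overlapping and antisense genes cannot be separated. Within each library every value was a whole multiple of the value of 1 read (1.13 in All-EV, 1.04 in Ocn-EV and 0.872 in Prx1-EV), for 100% of values at a tolerance of 1e-06. Whole reads were recovered by that division. The implied size factors (0.884, 0.966 and 1.15) differed from median-of-ratios factors recomputed from the reads (0.892, 0.975 and 1.16) by a nearly common factor, and ratios between libraries differed by at most 0.0409%. The libraries held 15558165 (All-EV), 14233978 (Ocn-EV) and 17269204 (Prx1-EV) reads assigned to genes.

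The table has 27179 genes, listed by gene identifier. Symbols, positions and gene types came from a RefSeq table of GRCm38.p6, the same build as mm10, and matched 25275 identifiers, leaving 1904 without a symbol. Genes with a mean value of at least 50 over the 3 libraries (11067, of which 89 had no symbol) entered all comparisons. Transcript length and GC content came from GENCODE vM21 transcripts, the longest per gene, for 10798 of these genes (97.6%).

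With 1 library per group no test between conditions is possible. For each pair of groups, log2((a + 1)/(b + 1)) was computed from the deposited values. The pseudocount pulls ratios of low genes toward 0. Folds are plain ratios of deposited values. Genes at least 2-fold apart were counted, and 95% exact conditional binomial intervals (Clopper-Pearson) of the ratio were computed from the recovered reads. Reads without molecular identifiers are not independent molecules, so intervals cover counting error only. The floor for a gene at 0 reads was 3 reads in that library (3.40, 3.11 and 2.62 in deposited units). Shares of reads carry exact Clopper-Pearson intervals. An exact conditional binomial test on the recovered reads with Benjamini-Hochberg adjustment, which compares the 2 libraries and not the conditions, called 7134 (Ocn-EV against All-EV), 7092 (Prx1-EV against All-EV) and 2840 (Ocn-EV against Prx1-EV) genes. These calls set no direction in the text. The 2-fold genes included 1159, 972 and 54 of the called genes.

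The 45 gene lists, the named-gene rule, the filter, the thresholds and the alternatives were fixed before the data were examined, except the removal of the length and GC trend and the test on reads, which were added afterwards. A list with at least 5 members at the expression filter was given the median log2 ratio of its members and the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. A median outside the central 95% of the random medians placed a list outside the limits, as a description of these libraries. Under each alternative 10000 random lists were drawn from the same random seed. Members at least 1.5-fold higher or lower were counted. By the rule, genes with a plain symbol were named when among the 12 highest or 12 lowest ratios of a comparison, among the 8 highest or 8 lowest common to both comparisons with All-EV, among the 4 members of a list outside the limits that lay farthest from 0 in the direction of its median, or on a list of 18 genes fixed in advance. The genes Gpnmb, Psap, Ctsb, Lyz2, Itgam, Ctss, Adgre1, Mmp12, Mmp13, Icam1, Lif, Irf1, Ccl2, Mmp8, Pf4, Tsix and the Y-linked genes, and single members given for lists in the closing section, were chosen after their values were seen.

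Both comparisons with All-EV share its library, so 1000 sets of unchanged libraries with counting noise were simulated for the correlation and for the number of 2-fold genes from noise alone. The calculations were tested on simulated data with 200 genes changed by known folds among 11067. In the simulations of Ocn-EV against All-EV, 98% of 50 genes changed 3-fold and 100% of 50 changed 4-fold were recovered, 0% of 50 changed 1.5-fold passed 2-fold, 1 of 10867 unchanged genes was called, and 95.5% of intervals held the true ratio. Of 34 unchanged lists, 0, 4 and 4 lay outside the limits in the 3 comparisons. Pseudocounts, expression filters, scalings and the size threshold were varied, and the trend of the ratios on transcript length and GC content was removed by LOWESS (fraction 0.3). Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.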

Results

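Mouse bone marrow stromal cells were kept at 3% oxygen and exposed for 3 days to extracellular vesicles, small membrane particles that cells release, taken from mouse bone marrow plasma. Ocn-EV vesicles came from mice in which a Snorkel transgene was combined with the Ocn (osteocalcin) Cre driver, which is active in mature osteoblasts. Prx1-EV vesicles came from mice with the Prx1-Cre driver, which is active in limb mesenchyme and its descendants. All-EV vesicles came from wild-type mice and served as the control. Plasma of 5 mice (2 males and 3 females, 6 months old) was pooled for each vesicle preparation. RNA of the treated cultures was sequenced as 1 messenger RNA library per group. There were no replicates (n = 1 in each group), so no difference described here has a replicate check and no p-value is given. The libraries held 15558165 (All-EV), 14233978 (Ocn-EV) and 17269204 (Prx1-EV) gene-assigned reads, with 16962, 17291 and 17303 genes that had a read. Levels are the deposited normalised counts, and bracketed ranges are 95% intervals that cover counting error only. "Higher" and "lower" compare single libraries.

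The cultures contained abundant macrophage transcripts beside stromal ones in all 3 libraries. The 10 genes with the most reads took 16.33% (16.31 to 16.35) of the reads in All-EV, 11.77% (11.76 to 11.79) in Ocn-EV and 12.25% (12.23 to 12.26) in Prx1-EV, and 7 of them were shared by the 3 libraries, among them the lysosomal genes Gpnmb, Psap, Ctsb and Ctsd. The 20 genes of a macrophage list took 1.84% (1.84 to 1.85), 1.41% (1.40 to 1.42) and 1.25% (1.24 to 1.26) of reads in All-EV, Ocn-EV and Prx1-EV. A summed share follows its most abundant members, and Lyz2 of this list was among the 10 genes with the most reads in All-EV alone. The 25 genes of a collagen and fibrillar matrix list took 0.297% (0.294 to 0.299), 1.37% (1.37 to 1.38) and 0.982% (0.977 to 0.987). A stromal progenitor list took 0.0217% (0.0209 to 0.0224), 0.0469% (0.0458 to 0.0480) and 0.0395% (0.0385 to 0.0404). The 21 genes of an osteoblast list took 0.638% (0.634 to 0.642) in All-EV, 0.677% (0.673 to 0.681) in Ocn-EV and 0.484% (0.481 to 0.487) in Prx1-EV. Of the reads of that list, Spp1 alone held 85224 of 99262 in All-EV, 16249 of 96331 in Ocn-EV and 19792 of 83593 in Prx1-EV.

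The first comparison asked how stromal cultures given vesicles of the Ocn-Cre mice differed from those given the control vesicles. Matrix, bone-forming, contractile and interferon-stimulated genes were higher with Ocn-EV, while inflammatory chemokine, ribosomal protein and oxidative stress genes were lower. Col1a1, the main chain of type I collagen, stood at 44981 with Ocn-EV against 7861 with All-EV, a log2 ratio of 2.52 (2.48 to 2.55). Ibsp, the bone sialoprotein of mineralising osteoblasts, stood at 948 against 19.2 (log2 5.55, 4.94 to 6.41). Fgfr2, a fibroblast growth factor receptor, had 127 reads with Ocn-EV and 0 with All-EV. It was 38.7-fold higher with All-EV set at the floor of 3 reads, and the lower limit of its log2 interval was 4.96. At the other end, the acute-phase gene Saa3 stood at 4.14 against 1538 (log2 −8.23, −10.41 to −7.18), and the macrophage scavenger receptor Marco at 13.5 against 2455 (log2 −7.41, −8.42 to −6.73).

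Of the 11067 genes with a mean level of at least 50, 1159 were at least 2-fold apart between Ocn-EV and All-EV, 694 higher and 465 lower with Ocn-EV. Simulated libraries with counting noise alone gave at most 3 such genes in 1000 simulations. The log2 ratios had an SD of 0.71 across genes, against 0.13 from counting noise. The share of higher genes among these depended on scaling, at 59.9% as deposited and 81.8% with libraries set to equal totals. That rescaling put the median log2 ratio of the tested genes at 0.24 for Ocn-EV and 0.22 for Prx1-EV against All-EV.

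The other genes with the highest ratios to All-EV were Mx1, Megf6, Scgb1a1, Slc13a5, Ccn5, Susd5, Hspb7, Cbr2, Igfbp5 and Gpr34. Mx1, an interferon-induced gene annotated here as a transcribed pseudogene, with 3 reads in All-EV and 119 in Ocn-EV, had a log2 ratio of 4.82 (3.60 to 7.48). Igfbp5, an insulin-like growth factor binding protein gene, stood at 1195 against 73.6, 16.2-fold higher. The lowest ratios belonged to Saa3, the neutrophil-attracting chemokine Cxcl3, Marco, the gelatinase Mmp9, Ccl5, Tarm1, Slpi, Treml4, Serpinb9b, Bst1, the inducible nitric oxide synthase Nos2 and Sema3c. Cxcl3 had 181 reads in All-EV and 0 in Ocn-EV. It was 65.9-fold lower with Ocn-EV set at the floor of 3 reads, and the upper limit of its log2 interval was −5.73. Mmp9 was 72.8-fold lower and Nos2 19.2-fold lower.

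The bone and matrix lists were higher as groups, in a library where the macrophage list took 1.41% of reads against 1.84% in All-EV. That summed share is no measure of macrophage number, since the list's median log2 ratio was 0.19, with 7 of 20 members higher and 5 lower. In the collagen and fibrillar matrix list, 20 of 21 tested members were at least 1.5-fold higher with Ocn-EV and none was lower by that amount (median log2 2.10, percentile 100 of 10000 random lists matched on expression). Col5a1 and Col12a1 had log2 ratios of 2.93 and 2.82. In the osteoblast list, 9 of 11 tested members were higher and 1 was lower (median 2.47, percentile 100). Sp7, the transcription factor of osteoblast commitment, stood at 179 against 13.6, and the bone alkaline phosphatase Alpl at 764 against 118. Runx2 did not differ beyond counting error (log2 0.25, −0.02 to 0.51). The lower member was Spp1, which encodes the matrix protein osteopontin and is also made by macrophages, at 16825 against 96446, 5.73-fold lower. Bglap, the osteocalcin gene itself, had 0 reads in All-EV, 4 in Ocn-EV and 0 in Prx1-EV, too few to compare.

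**Figure D1:**
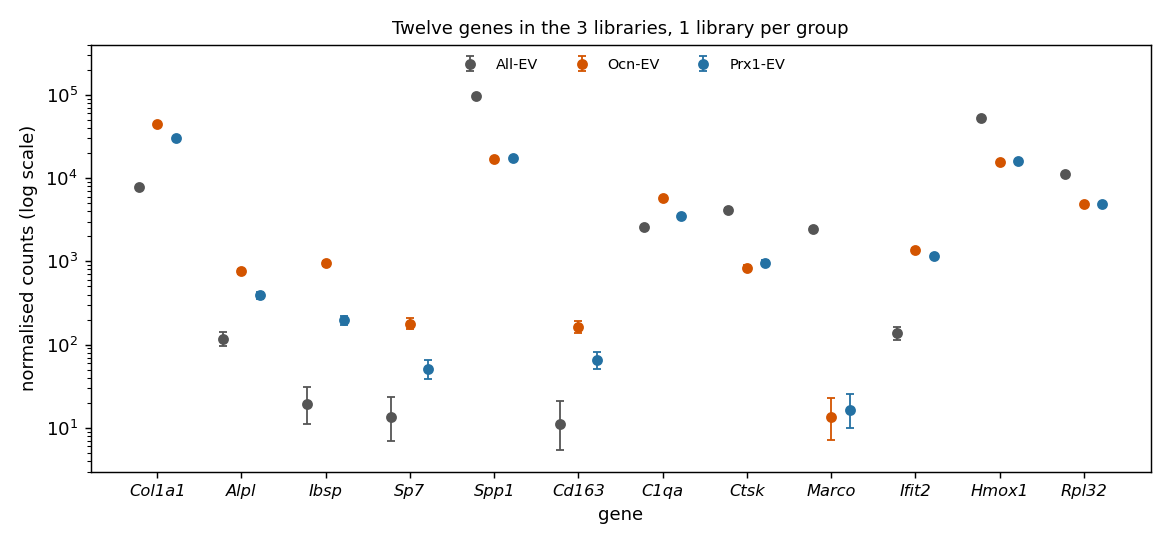
Normalised counts (log scale) of 12 genes in the 3 libraries, 1 point per library, with 95% intervals of counting error. Col1a1, Alpl, Ibsp and Sp7 lie above All-EV in both other libraries, and Spp1, Ctsk, Marco, Hmox1 and Rpl32 lie below it; under other scalings tried these directions did not turn.

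Stromal and smooth muscle genes were higher too. In the contractile and myofibroblast list, 14 of 17 members were at least 1.5-fold higher with Ocn-EV (median 1.39, percentile 100), among them smooth muscle myosin Myh11 (log2 3.03) and the myosin light chain Myl9 (1.79). The YAP and TAZ target list had 11 of 13 members higher (median 0.92), with Ajuba at 1.59 and Ccn1 at 1.58. Of the Wnt list, 6 of 8 tested members were higher (median 1.42), led by Rspo2 at 3.72, Nkd2 at 2.64, Ccn4 at 1.73 and Dkk3 at 1.72. This list mixes targets and regulators of the pathway, so its median gives no direction of Wnt signalling. The stromal progenitor list had 8 of 13 higher and 2 lower (median 0.99), with Pdgfrb at 2.06 and Prrx1, the gene whose regulatory region drives Prx1-Cre, at 1.24. The osteoclast regulator list had 3 of 5 higher (median 0.96), the decoy receptor Tnfrsf11b at 2.17, Cxcl12 at 1.08 and the growth factor Csf1 at 0.96. In this list 1 was lower, the chemokine Ccl2 at −1.94 (−2.32 to −1.60). The matrix remodelling list was mixed, with 9 of 21 members higher and 5 lower (median 0.31). Its crosslinking enzyme Lox stood at 1.57, whereas the proteases Mmp9, Mmp13, Ctsk and Mmp12 stood at −6.15, −3.04, −2.31 and −1.84. The TGF-beta and BMP list (median 0.37, Tgfb3 at 3.16) and the endothelial list (median 0.56, with 4 of 8 higher and 1 lower) lay above the random lists, but not after removal of the trend on transcript length and GC content (medians 0.17 and 0.37, percentiles 96.1 and 94.7).

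Interferon-stimulated genes, which cells switch on during antiviral responses, were higher in 23 of 27 tested members and lower by 1.5-fold in 0 (median 1.53, percentile 100). Ifit2 stood at 1356 against 137, and Ifit3 at 558 against 57. The NF-kB cytokine and chemokine list had 12 of 20 members lower and 3 higher (median −1.10, percentile 0). Complement C3 had a log2 ratio of −3.97 and the chemokine Cxcl2 −4.16. The higher members of this list were Icam1, Lif and Irf1. Reads of 2 blood cell lists were also fewer with Ocn-EV than with All-EV, at 0.0115% against 0.0540% for neutrophil genes, which in All-EV were mostly Mmp8, and 0.0202% against 0.0675% for megakaryocyte and platelet genes, mostly Pf4. The osteoclast list had 4 of 7 lower and 2 higher (median −1.05), with the bone-resorbing protease Ctsk at 843 against 4185 and tartrate-resistant phosphatase Acp5 at 222 against 659. With no expression filter its median was −0.07.

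Macrophage markers differed among themselves. With Ocn-EV, 7 of 20 members were at least 1.5-fold higher and 5 lower than with All-EV (median 0.19, percentile 98.7), and 8 higher and 4 lower with libraries set to equal totals (median 0.45). The scavenger receptor Cd163 stood at 165 against 11.3, C1qa at 5730 against 2568 and the mannose receptor Mrc1 at 11111 against 6024. Lyz2, Itgam, Ctss and Adgre1 had log2 ratios of −1.44, −1.42, −0.95 and −0.70.

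**Figure D2:**
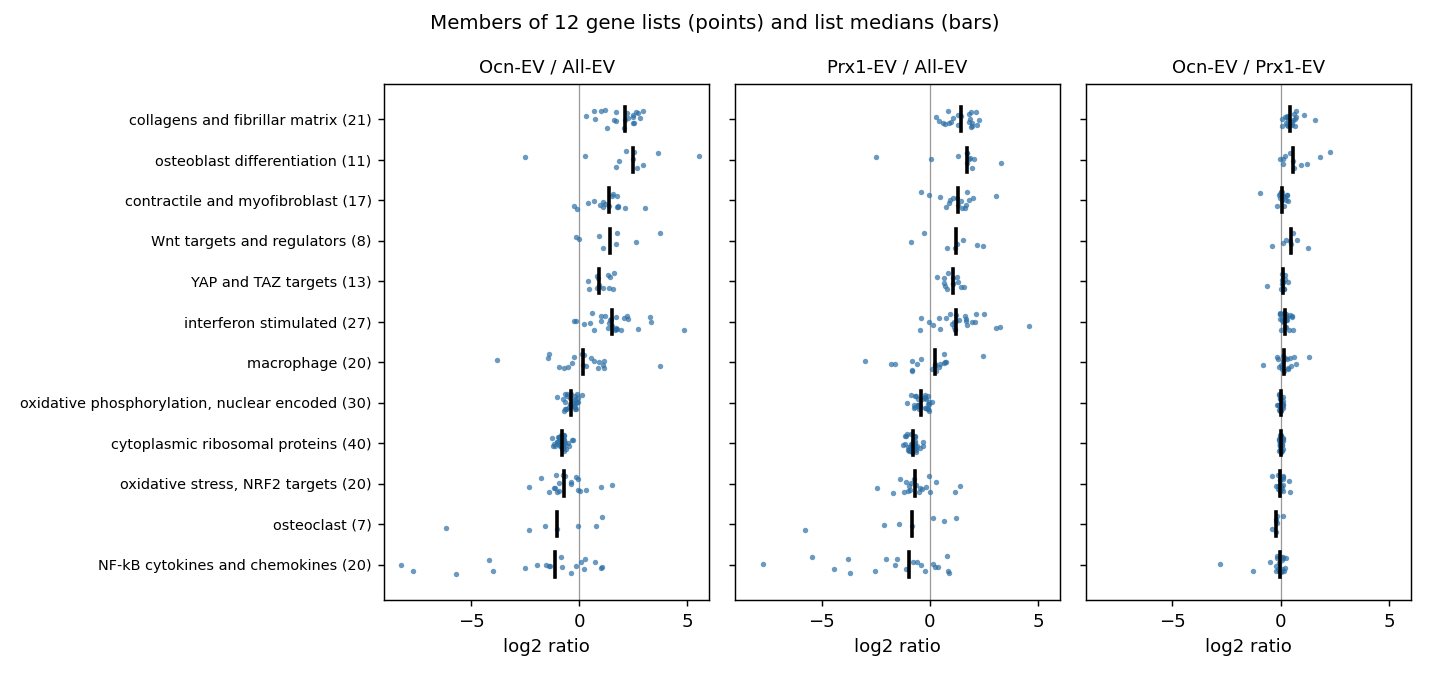
Log2 ratios of the members of 12 gene lists (points, 1 gene each) and list medians (black bars) for the 3 comparisons, numbers of tested members in brackets. Collagen, osteoblast, contractile, Wnt, YAP and interferon medians lie to the right of 0 against All-EV, and the ribosomal, NRF2, osteoclast and NF-kB medians to the left, while between Ocn-EV and Prx1-EV the osteoblast (0.57), Wnt (0.46) and collagen (0.43) medians lie farthest to the right of 0; the ribosomal median of that last comparison changed sign with the scaling.

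Genes for making proteins and handling oxidative stress were lower with Ocn-EV. All 40 cytoplasmic ribosomal protein genes were tested and 36 were at least 1.5-fold lower (median −0.78, percentile 0), led by Rpl35 (−1.23) and Rpl32 (−1.21). With libraries set to equal totals, the median was −0.53 and 13 of 40 passed 1.5-fold. Removal of the length and GC trend gave a median of −0.54, also with 13 of 40 lower by 1.5-fold. Many of these genes have near-identical pseudogene copies, so their reads are less certain. The NRF2 target list had 11 of 20 lower and 2 higher (median −0.69, percentile 0.03), among them heme oxygenase Hmox1 at 15684 against 52623 and the cystine carrier Slc7a11 at log2 −2.34. The unfolded protein response and ATF4 list had 11 of 26 lower (median −0.37, percentile 0.71), with Ddit3 at −1.49 and Trib3 at −1.41. Nuclear genes of oxidative phosphorylation had 8 of 30 lower (median −0.37, percentile 0.06), but the median was −0.07 after the length and GC trend was removed. The lysosome list (7 of 25 lower, median −0.40, percentile 2.03) lost its place outside the random lists after that step (percentile 5.45). With libraries set to equal totals, the medians were −0.44 for NRF2 targets (9 lower and 2 higher), −0.11 for the unfolded protein response list (7 lower and 1 higher), −0.12 for oxidative phosphorylation (1 lower) and −0.14 for the lysosome list (2 lower and 1 higher). The same rescaling gave medians of 0.57 for matrix remodelling, 0.63 for TGF-beta and BMP and 0.75 for histone genes.

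The histone list, led by the replication-independent linker histone H1f0, lay just above the random lists (median 0.50 over 5 members, percentile 97.6), but not with a lower expression filter (percentile 86.2). Of its 5 members, 1 was at least 1.5-fold higher and 2 were lower as deposited, and 3 were higher and 2 lower with equal totals. In total 20 of 34 testable lists lay outside the central 95% of random lists, where 1.7 lists of randomly drawn genes would. Genes of a list can vary together between any 2 cultures, so this number does not set culture variation aside, and many lists share members.

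The next comparison asked the same of vesicles from Prx1-Cre mice. Matrix, bone-forming, contractile and interferon-stimulated genes were again higher than with All-EV, and inflammatory chemokine, ribosomal protein and oxidative stress genes lower. Col1a1 stood at 30399.5 against 7861 (log2 1.95, 1.91 to 1.99), Ibsp at 195 against 19.2 (3.28, 2.63 to 4.15) and Alpl at 393 against 118 (1.73, 1.43 to 2.06). Saa3 was 44.1-fold lower, Marco 148-fold lower and Mmp9 54.7-fold lower. Fgfr2 had 46 reads against 0, and Cxcl3 had 0 reads. With the empty library set at the floor of 3 reads they were 11.8-fold higher and 78.3-fold lower. The limits of their log2 intervals nearest 0 were 3.21 and −5.98. Spp1 was 5.59-fold lower.

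Between Prx1-EV and All-EV, 972 genes were at least 2-fold apart, 567 higher and 405 lower, with at most 3 from counting noise. The share of higher genes was 58.3% as deposited and 79.6% with equal totals. Beside Fgfr2, Mx1 and Ibsp, the highest ratios belonged to Megf6, Scgb1a1, Gpr34, Cbr2, Hspb7, Fcrls, Slc13a5, Alkal1 and Susd5. Fcrls, an Fc receptor-like gene of macrophage lineage cells, stood at 6453 against 569. The lowest ratios again included Marco, Mmp9, Slpi, Tarm1, Bst1, Nos2 and Ccl5, with Treml4 at 3 reads against 192 (log2 −5.92, −8.67 to −4.81). They also included the long noncoding RNAs Mirt2 (−4.99, −7.24 to −3.95) and Xist (−5.69, −7.39 to −4.80). Xist, the RNA that silences an X chromosome in female cells, stood at 320 in All-EV, 126 in Ocn-EV and 5.23 in Prx1-EV. It overlaps its antisense partner Tsix, and whether counting used strand is not given in the sources used here.

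By list, 19 of 21 collagen and matrix members were higher with Prx1-EV (median 1.45), 9 of 11 osteoblast members (1.73), 14 of 17 contractile members (1.32), 12 of 13 YAP and TAZ targets (1.05), 6 of 8 Wnt genes (1.22), 7 of 13 stromal progenitor genes (0.61) and 21 of 27 interferon-stimulated genes (1.21), the last with 0 lower. Lower by 1.5-fold were 1 osteoblast, 1 Wnt and 2 stromal progenitor members. All 7 medians lay at percentiles of 99.97 or above, while the macrophage list took 1.25% of reads against 1.84% in All-EV. Myh11 (log2 3.04), Rspo2 (2.46) and Ifit3 (3.22) were among the members farthest from 0. The osteoclast regulator list (3 of 5 higher and 1, Ccl2, lower; median 0.61, percentile 99.1) lay inside the limits after the length and GC correction (percentile 96.8) and with a lower expression filter (92.2). The matrix remodelling (0.32), macrophage (0.24) and histone (0.49) lists were above the limits with members on both sides. Remodelling genes had 7 of 21 higher and 5 lower as deposited, and 10 higher and 5 lower with libraries set to equal totals (median 0.55). The histone median was 0.71 with equal totals. The histone list lay inside them with a filter of 10 (0.19, percentile 78.7) and with no filter (0.24, percentile 84.5). Of the 20 macrophage members, 5 were higher and 7 lower as deposited, but 7 were higher and 5 lower both with equal totals (median 0.47) and after the length and GC trend was removed (0.15). Among them, Cd163 stood at 65.4 against 11.3 and Itgam at 7532 against 22791.

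The NF-kB list had 12 of 20 lower and 3 higher (median −0.95), ribosomal proteins 37 of 40 (−0.80; 19 of 40 and −0.58 with equal totals; −0.53 with the length and GC trend removed), NRF2 targets 11 of 20 and 2 higher (−0.70) and the osteoclast list 4 of 7 and 2 higher (−0.83, but 0.15 with no expression filter). Oxidative phosphorylation genes had 7 of 30 lower (−0.41, and −0.02 after the length and GC trend was removed). The unfolded protein response and ATF4 list had 7 of 26 lower (−0.27, percentile 2.13), and lay inside the limits with a filter of 200 (−0.21, percentile 8.47) and after the length and GC trend was removed (−0.21, percentile 6.65). With libraries set to equal totals, its median was −0.05 with 4 lower and that of oxidative phosphorylation −0.19 with 2 lower. Neutrophil list genes took 0.0128% of reads with Prx1-EV against 0.0540% with All-EV, and megakaryocyte and platelet genes 0.0203% against 0.0675%. Of 34 lists, 17 lay outside the limits. TGF-beta and BMP targets (0.09), endothelial genes (0.25) and lysosome genes (−0.33) lay inside them, and whether they differ from their Ocn-EV values was not tested. With equal totals these medians were 0.32, 0.47 and −0.11. The lysosome list lay below the limits with a filter of 10 (percentile 1.845) and with no filter (1.41).

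**Figure D3:**
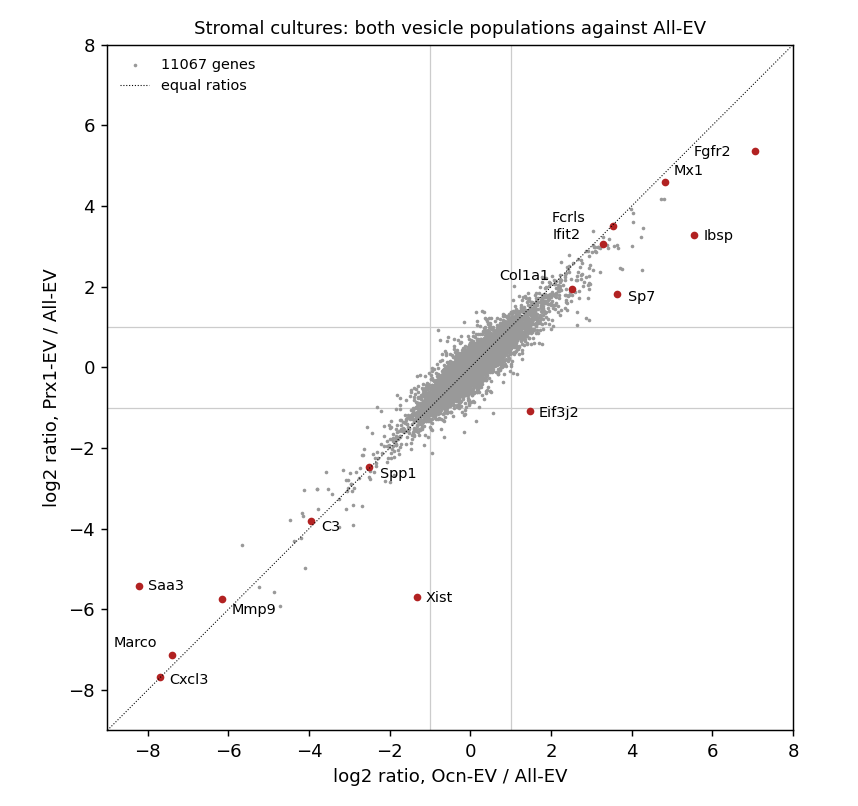
Log2 ratio to All-EV of Prx1-EV (vertical axis) against that of Ocn-EV (horizontal axis) for 11067 genes, 1 point per gene, with grey lines at 2-fold and a dotted line of equal ratios. Most genes lie along the line (r = 0.931 across genes), Ibsp, Fgfr2 and Sp7 lie to its right, and Xist and Eif3j2 lie apart from it.

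The Ocn-EV and Prx1-EV log2 ratios to All-EV were alike across genes, with Pearson's r of 0.931 and Spearman's rho of 0.900, where genes are not independent replicates. Both ratios use the same All-EV library, and unchanged libraries simulated against it gave a mean r of 0.544, with single simulations from 0.513 to 0.578. The covariance was 0.434 against 0.00923 in those simulations, a difference of 0.425. That difference also holds whatever set the single All-EV culture apart. Of the genes 2-fold apart, 483 were higher in both, where independent lists would share 35.6, and 326 were lower in both, where they would share 17.0. Part of this excess may come from the shared control, which cannot be split. Only Eif3j2 was 2-fold higher in 1 and 2-fold lower in the other. It has a near-identical copy, Eif3j1, so its reads are uncertain.

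The last comparison set both tagged vesicle preparations against each other. Bone-forming and matrix genes were higher with Ocn-EV than with Prx1-EV. Ibsp stood at 948 against 195 (log2 2.27, on 916 reads against 224), Sp7 at 179 against 50.6 (1.80, 1.39 to 2.28), Ccn5 at 452 against 126 (1.84, 1.57 to 2.13), the fibrillar collagen Col11a1 at 575 against 192 (1.58, 1.35 to 1.81) and the parathyroid hormone receptor Pth1r at 1.22 (0.93 to 1.53). Col1a1 had a log2 ratio of 0.57 (0.54 to 0.59) and Alpl of 0.96 (0.79 to 1.13). Saa3 was lower with Ocn-EV (−2.80, −5.02 to −1.61, on 4 reads against 40).

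Only 57 genes were at least 2-fold apart, 36 higher and 21 lower with Ocn-EV, against at most 2 from counting noise, and the SD across genes was 0.26 against 0.12 from counting. Most were of low expression, since 8 of them had a mean of at least 200 and a pseudocount of 10 left 34. Genes higher with Ocn-EV also included Xist (24.1-fold), Eif3j2, the fractalkine receptor Cx3cr1, Trem1, Fgfr2 (3.28-fold), the hyaluronan-degrading Cemip, Znrd1as and Gzme. Those lower included Cd300ld3, Dusp18, Bbs10, Nup210, Shroom4, Fam110c, Raet1e, Cdk15 and the immunoglobulin genes Ighv6-6 and Ighg2b, which belong to families of similar sequence. Ccl5 lay within counting error (−1.26, −3.53 to 0.24).

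In the osteoblast list 5 of 11 members were at least 1.5-fold higher with Ocn-EV and 0 lower (median 0.57, percentile 100), and in the collagen list 7 of 21 and 0 (0.43, percentile 100). The Wnt list had 2 of 8 higher (0.46), led by Rspo2 (1.26). Mitotic genes had 7 of 23 higher and 0 lower (0.24, percentile 99.2), among them Plk1 (1.01) and Cenpf (0.85), while Mki67 stood at 0.50 (0.33 to 0.67). DNA replication genes had 2 of 21 higher (0.20, percentile 99.8), with Mcm5 at 0.82. Macrophage genes had 3 of 20 higher and 1 lower (0.15, percentile 100), with Cd163 at 1.32 and C1qa at 0.70. Smaller medians above the random lists were found for interferon-stimulated (0.22), cholesterol synthesis (0.21), senescence (0.19), TGF-beta and BMP (0.18), adipocyte (0.15) and contractile genes (0.07). Few of their members were 1.5-fold higher, at 0 of 27, 1 of 23, 1 of 17, 1 of 17, 1 of 11 and 0 of 17 in that order. Of the contractile genes, 1 was lower. The osteoclast (−0.20), histone (−0.20), unfolded protein response (−0.17) and hypoxia and glycolysis (−0.13) medians lay below. Almost none of their members were 1.5-fold lower, at 0 of 7, 0 of 5, 1 of 26 and 0 of 27 in that order. The ribosomal protein median was −0.0008, which lay above the random lists (percentile 99.6). It changed sign with each rescaling, which shifts nearly all genes alike, and kept that percentile, so no direction from 0 is given for it. After the length and GC trend was removed it lay inside the limits (−0.03, percentile 92.4), as did the adipocyte median (0.08) and the histone median (−0.17), and the senescence median was 0.11. The Wnt, DNA replication, adipocyte, senescence and histone lists lay inside the limits under at least 1 other expression filter, and the senescence median was −0.0016 at a filter of 200. In the other direction, the stromal progenitor (0.12) and matrix remodelling (0.02) lists lay inside the limits at the main filter but above them under each other filter. The YAP and TAZ list (0.09) lay above them with a filter of 200 and with none. In all, 17 of 34 lists lay outside the limits.

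The vesicle genes Cd81, Cd63 and Cd9, named in advance, differed by less than 1.5-fold. Cd81 was at the top of the vesicle biogenesis list in both comparisons with All-EV. Cd81 had log2 ratios of 0.56 and 0.51 for Ocn-EV and Prx1-EV against All-EV, Cd63 of −0.04 and 0.02 and Cd9 of −0.15 and −0.12. The vesicle biogenesis list lay inside the limits in each comparison (medians −0.16, −0.12 and −0.05). Of its 22 tested members, 3 were at least 1.5-fold lower than All-EV with Ocn-EV and 2 with Prx1-EV, and 0 were higher with either. With equal totals 1 was lower and 1 higher with Ocn-EV, and 0 lower and 1 higher with Prx1-EV. Against All-EV the sign of the list's medians turned with equal totals (0.099 and 0.102) and with the length and GC trend removed (0.006 and 0.025). Cxcl12 stood at 1.08 and 0.61, Pparg at 0.52 and 0.24, Cdkn1a at 0.04 and 0.14, and Mki67 at 0.06 and −0.44. Sox9 lay below the expression filter at 47.5, 24.9 and 27.9, Adipoq had 0 reads in each library, and Tnfsf11 had 0, 4 and 3. Several further lists lay inside the limits of all 3 comparisons: Notch, antigen presentation, p53, mitochondrially encoded, fatty acid synthesis, heat shock and immediate early genes, with medians against All-EV from −0.46 to 0.19. Under a filter of 200, immediate early genes lay below the limits for Prx1-EV against All-EV (−0.36, percentile 0.78). Mitochondrially encoded genes lay above them between Ocn-EV and Prx1-EV with that filter (percentile 97.6) and with the length and GC trend removed (99.35). Adipocyte, senescence, DNA replication, mitotic, cholesterol synthesis and hypoxia and glycolysis genes lay inside the limits in both comparisons with All-EV, with medians from −0.42 (hypoxia and glycolysis, Ocn-EV) to 0.24 (adipocyte, Prx1-EV). With a filter of 10 the adipocyte list lay above them in both (0.47 and 0.36, percentiles 99.5 and 98.3). With Ocn-EV and the length and GC trend removed, senescence genes lay above them (percentile 98.2) and hypoxia and glycolysis genes below (2.425).

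In GRCm38 coordinates the genes named most often lie at chromosome 11, 94936224 to 94953042 (Col1a1), chromosome 5, 104299287 to 104311472 (Ibsp), chromosome 15, 102356603 to 102367035 (Sp7), chromosome 7, 130162451 to 130266808 (Fgfr2), chromosome 7, 46711998 to 46719615 (Saa3), chromosome 1, 120474538 to 120505024 (Marco), chromosome 5, 104435111 to 104441053 (Spp1) and chromosome X, 103460373 to 103483233 (Xist). All are whole annotated genes, and the values sum reads over each gene.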

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

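The tests of the length and GC trend, of the macrophage share, of the All-EV library itself and of Xist were chosen after the data were seen, and the bounds for the test of a common stromal factor were set before its result was seen.

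Among named genes, 6 had ratios to All-EV of opposite sign as deposited with Ocn-EV and with Prx1-EV, with both counting intervals clear of 0. With 1 library each the difference was not tested. Trem1 had log2 ratios of 0.56 with Ocn-EV and −1.14 with Prx1-EV, and Eif3j2 of 1.47 and −1.09. Cd300ld3 had −0.80 and 0.93, Dusp18 −0.75 and 0.68, and Ighg2b −0.55 and 0.75. Atp6v0d2 had −0.059 and 0.15, a split that depends on the scaling, since equal totals raised the median Ocn-EV ratio to 0.24.

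Ocn-EV and Prx1-EV differed from All-EV with alike ratios across genes. Length and GC content do not account for it as a whole, since 80.3% of the 2-fold genes (Ocn-EV against All-EV) stayed 2-fold apart in their direction after that trend was removed. A lower share of macrophages as the sole cause is argued against by 7 macrophage genes, among them Cd163 and C1qa, that were at least 1.5-fold higher with Ocn-EV with intervals above 0 while 5 were lower, although a shift in macrophage state together with share stays open. With 1 All-EV library, a difference of that culture itself and an effect of the vesicles cannot be told apart. How vesicles of wild-type mice were captured with an HA antibody is not given in the sources used here and was not tested.

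Bone and matrix genes were higher with Ocn-EV than with Prx1-EV. A larger share of stromal cells in the Ocn-EV culture is a candidate explanation, and would raise stromal genes by 1 common factor. The 23 genes examined were members of the collagen, osteoblast and stromal progenitor lists at least 2-fold higher than All-EV with both preparations. That choice drew on these same data and holds genes of the pattern itself, so their direction adds no support. Of the 23, 22 were higher with Ocn-EV, with a median log2 ratio of 0.55, and 17.4% of their counting intervals held that median. That low share argues against 1 exact common factor in these 2 libraries. The intervals cover counting error only, so variation between single cultures could also make them miss the median. The ratios' interquartile range was 0.385, under the bound of 0.5 also set, so the explanation stays open. Whole stromal lists were mixed between Ocn-EV and Prx1-EV and do not decide. The stromal progenitor list had a median of 0.12, inside the limits, with 1 of 13 members higher. With filters of 10 and 200 that median was 0.30 and 0.33, above the limits. The contractile list had a median of 0.07, with 0 of 17 members higher and 1 lower. Osteoblast list genes lay on both sides of the 0.55 median (Ibsp 2.27 and Sp7 1.80, but Mef2c 0.10 and Tnfrsf11b 0.13), and an effect of the vesicles is also open.

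The Xist level differed between libraries by far more than counting error. It was 61.2-fold higher in All-EV than in Prx1-EV (27.8 to 168). Carry-over of vesicle RNA stays open, since that fold is the pattern itself and so no test of it. A small share of female cells in the All-EV culture may explain its level there, but would not account for the 24.1-fold higher level in Ocn-EV than in Prx1-EV. Female shares that differ among all 3 cultures were not tested and stay open. The 4 Y-linked genes had a median log2 ratio of −0.0143 of All-EV over Prx1-EV. Single genes ran from −0.41 (Kdm5d) to 0.29 (Eif2s3y), each with a counting interval clear of 0, so they went both ways and do not decide. An effect of the vesicles on Xist in the cells was not tested.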

How the results depend on the processing

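The removal of the length and GC trend and the test on recovered reads were chosen after the data were seen. Each comparison has 1 library per group, so leaving out columns and limma over columns were not run. No paired analysis was possible because each group has 1 library. The number of 2-fold genes was within 1.5 times of that reported under the rescalings and the trend removal. It depended on the expression filter and on the size threshold. The number of genes tested does not alone account for this. Between Ocn-EV and Prx1-EV, 8 of 8180 tested genes passed with a filter of 200 and 2669 of 18745 with none. For Ocn-EV against All-EV the number of 2-fold genes was 1894 with a filter of 10, 678 with 200 and 4816 with none, and 3034 genes passed at 1.5-fold. For Prx1-EV against All-EV it was 1695, 579, 4052 and 2802. For Ocn-EV against Prx1-EV it was 429, 8, 2669 and 392, and 34 with a pseudocount of 10. The test on reads, which has no size threshold, called 7134, 7092 and 2840 genes in the 3 comparisons. The correlation across genes was 0.736 with no filter and within 0.1 of the reported value otherwise. Of the medians of lists outside the limits, 5 changed sign: senescence (Ocn-EV against Prx1-EV) to −0.0016 with a filter of 200, osteoclast (Prx1-EV against All-EV) to 0.149 with no filter, and ribosomal proteins (Ocn-EV against Prx1-EV) to 0.0308 with equal totals, 0.0127 with a median of 0 and 0.0126 with equal upper quartiles. Rescaling shifts nearly all genes alike, which accounts for the ribosomal changes, and no list crossed the limits with a rescaling. The cause of the other 2 changes was not tested. Of the other list medians under the alternatives, 26 moved inside the limits, 20 moved outside them, 29 that lay inside changed sign by at least 0.1, and 718 did none of these. No named gene at least 2-fold apart changed sign, and 2069 values of named genes stayed within their counting intervals and 243 left them. Shorter transcripts were lower with Ocn-EV and Prx1-EV than with All-EV (medians −0.33 and −0.36 under 1500 bases) and longer ones higher (0.15 and 0.17 over 6000), with Spearman's rho of 0.25 and 0.28 across genes. Depth limits low genes most, as 3 reads is the floor.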

Other observations

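The genes named here were chosen after their values were seen. Markers of other blood cells, from lists with too few expressed members to be tested, moved apart. The neutrophil collagenase Mmp8 stood at 8978 in All-EV, 836 in Ocn-EV and 1008 in Prx1-EV, the platelet chemokine Pf4 at 10461, 1817 and 1577, and its relative Ppbp at 126, 14.5 and 14.8. The immunoglobulin genes Ighm and Igkc had log2 ratios to All-EV of −1.80 and −1.05 with Ocn-EV and of −2.06 and −0.73 with Prx1-EV. Other members of the same lists were higher than in All-EV: Csf3r (1.11 with Ocn-EV and 1.21 with Prx1-EV), Treml1 (1.62 and 1.71), Ebf1 (1.24 and 1.40) and Cd4 (2.25 and 2.61). Il7r had ratios of −0.62 and −0.37 and Vwf of −0.48 and −0.04. Car2, from the erythroid list, lay within counting error at 0.17 and −0.17.

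The metal-binding metallothioneins were lower than in All-EV with both preparations, Mt1 at −1.54 with Ocn-EV and −1.48 with Prx1-EV and Mt2 at −2.76 and −2.74, whereas the zinc exporter Slc30a1 stood at 0.46 and 0.36. The cartilage collagen Col2a1 stood at 651 in All-EV, 7012 in Ocn-EV and 5950 in Prx1-EV. From the osteocyte list, Pdpn had ratios of −1.88 and −1.85, Ackr3 of 0.82 and 0.33 (the latter within counting error) and Cd44 of 0.11 and −0.05. The muscle genes Acta1 (0.85 and 1.15) and Des (1.08 and 2.01) were higher, the neural gene Nefl had ratios of −0.64 and −0.66, and the epithelial keratin Krt19 of −0.41 and 0.46. Inside the heat shock list, whose median lay within the limits, the stress-induced Hspa1a (2.40 and 1.61) and Hspa1b (2.70 and 1.90) were higher with both, but their sequences are near-identical, so the split of reads between them is uncertain. The immediate early gene Egr1 stood at 96.2 in All-EV, 651 in Ocn-EV and 471 in Prx1-EV, while Myc had a ratio of −1.31 with both.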
